A study of Acartia tonsa with 26 samples.

How the data were processed

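RNA-seq libraries were made from batches of eggs of the calanoid copepod Acartia tonsa. The 26 libraries form 6 groups. Of these, 23 come from subitaneous eggs, which develop without pause, at 3 h (4 to 16 cells, n = 5), 7 h (gastrulation, n = 5), 14 h (organogenesis, n = 4), 24 h (formation of appendages, n = 4) and 42 h (nauplii ready to hatch, n = 5). The other 3 come from quiescent eggs sampled at 26 h, after cold (4 °C) and anoxia had held them at gastrulation. Per the labels, adults lived in the dark in tanks of 60 L at a salinity of 32 and 16.9 °C, and each library started from 0.3 µg of total RNA (RNeasy extraction, TruSeq library kit). The replicates are described as technical, so the spread measured here is that between such samples, and the p-values do not cover variation between independent cultures. The sheet numbers in the labels repeat between letters A and B and letters C, D and E, from which 2 sequencing runs were inferred.

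The authors deposited 2 tables of genes of a de novo assembly, with normalized signal values for all 26 libraries in both. Per the labels, the genes were selected as differentially expressed at an alpha of 0.001 and a fold change of 2, among all subitaneous samples for 1 table (9502 genes) and between quiescent eggs and the 7 h and 14 h stages for the other (2777 genes). The tables share 2689 genes with identical values in both. Since every gene in them had already been selected on these samples, a call made here is not independent evidence. The submitters' processing notes list bcl2fastq and edgeR; the aligner, the counting tool, their versions and the scaling between libraries are not given in the sources used here. The deposited signal values keep whole reads: within a library 1 read was worth the same value for every gene, from 0.00894 to 0.0122 between libraries, so that a value of 1 stands for 81.8 to 112 reads. Of the 6890 to 9009 values per library of up to 2000 reads, 100% were whole within 0.1 of a step. The reads in the tables came to between 4.32e+06 and 2.42e+07 per library, which is not the full depth, because the tables hold selected genes only.

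Gene names are those in the assembly identifiers: the best protein match (4032 of 9590 genes), protein domains, and a signal peptide mark. The organism of the match was sorted into animal (2761 genes), plant or alga (497), fungus (231), protist (253), bacterium or archaeon (120), virus (15) and unclassified (155). Such a match names a related protein and is not an identification of the gene.

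Genes with a value of at least 1 in at least 3 libraries were tested, 5201 in the subitaneous table and 1682 in the quiescent table. The test was limma 3.58.1 (R 4.3.3) on log2(value + 1), with a group term, all 26 libraries sharing 1 estimate of spread, and eBayes with trend and robust. P-values were adjusted by Benjamini-Hochberg over the genes of a table, and a gene was called at an adjusted p under 0.05. Log2 changes are on the log2(value + 1) scale and understate the change of genes with low values; they are given with the standard error of the fit, and group levels as mean ± SD of the deposited values. Consecutive stages were compared in the subitaneous table, and quiescent eggs with 7 h and 14 h eggs in the quiescent table. For each gene of the subitaneous table the time with the highest mean was counted without a test. In simulated data with normal noise and 1 spread per gene shared by all groups, the fit called 34 to 45% of genes changed by 1 and 78 to 92% of genes changed by 2 on the log2 scale, with 6 to 9 unchanged genes called per comparison and 0 sign errors. Changes were added on the log2(value + 1) scale, where a simulated fall can pass below a value of 0. The shares thus do not hold for fold changes of genes with low values. The simulation also cannot show how many unchanged genes are called where groups spread unequally. For 42 h against 24 h, the spread of these 2 groups alone gave 197 genes in place of 2614.

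The test, the filter, 18 gene lists and the rule for named genes were fixed before the tables were opened. The plan named edgeR as the first test for a table of raw counts. Where whole reads can only be recovered, it listed edgeR and DESeq2 as alternatives to limma, with a remark that edgeR is the first choice for counts. The tables hold normalized values, so limma stayed first and edgeR counts stand beside it; that reading of the remark was settled after the tables were opened. The lists cover cell cycle and DNA replication, histones, chaperones, antioxidants, hypoxia and anaerobic metabolism, glycolysis, respiration, ribosome and translation, patterning factors, maternal and germ line factors, cuticle and chitin, moulting hormone, muscle, nervous system, proteases of digestion and hatching, lipid and yolk, stress proteins of dormant cysts, and algal or bacterial feed. Members that a name pattern caught in error were left out by name after the tables were read. Lists with fewer than 3 tested members could not be tested: hypoxia, glycolysis, maternal and germ line, moulting hormone and feed in both tables, and cell cycle in the quiescent table. Each list was counted over all genes tested and adjusted over the list alone, and set against the other genes with camera (preset correlation of 0.01, Benjamini-Hochberg over the lists of a comparison), then again with an estimated correlation. The fry test was run too; it asks whether the genes of a list move, on balance, in 1 direction, and does not compare them with other genes. Named genes are, per comparison and direction, the 5 called genes with the largest change, non-overlapping libraries, a mean of at least 10 in the higher group and a protein name (1 gene per name), and the up to 2 members of each list with the smallest adjusted p, called or not. The text names only members that were called, a narrowing made after the values were seen; the values of the others are in the results with theirs.

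Alternatives were a pseudocount of 0.1 or 5, no filter, a filter at a value of 5, rescaling by the median ratio, quantile normalization, the replicate letter as a block, a run term, A and B or C, D and E libraries alone, only the 2 groups compared, eBayes without trend and robust, an adjusted p of 0.001 with a log2 change of 2, and leaving out each replicate. Added after the values were seen were fits without the 42 h D library (with limma and edgeR) or without 42 h D and 24 h D, fits without the genes whose match is a plant, fungal, protist or bacterial protein, and lists restricted to animal matches. For the genes set against both stages the replicate block, both rescalings and the count models were added then too. Both rescalings were computed from the selected genes alone (4853 and 1432 for the median ratio in the subitaneous and quiescent tables). They take most genes as unchanged, and on genes selected as differing they can pull the median change towards 0. They therefore cannot decide which scaling gives the right balance of rises and falls. Count models were run on the recovered reads with the authors' scaling kept: edgeR 4.0.16 (quasi-likelihood) called 868, 2328, 368 and 2145 genes for the consecutive stages and 336 and 1201 for quiescent eggs against 7 h and 14 h, and DESeq2 1.42.0 was run beside it. On simulated reads with the estimated dispersion, edgeR recovered 0 to 11% and DESeq2 23 to 40% of genes whose reads changed by 2 on the log2 scale. A change of reads is another measure than a change of log2(value + 1), so these shares cannot be set against those of limma. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the rest. No reference genome was used, and no library was left out of the fits reported first.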

Results

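Eggs of the copepod Acartia tonsa were followed from the 4 to 16 cell stage at 3 h to nauplii ready to hatch at 42 h, beside quiescent eggs held at gastrulation. Of 5201 genes tested in the subitaneous table, 3231 had their highest mean at 42 h, 692 at 3 h, 688 at 24 h, 547 at 14 h and 43 at 7 h. The genes were selected by the authors as changing among these samples, so these counts and those below describe selected genes and are not independent evidence of change. Between consecutive stages 584, 1224, 647 and 2614 genes changed in turn from 3 h to 42 h, an order that other fits did not keep. The edgeR fit gave 868, 2328, 368 and 2145, and the spread of the 2 groups compared alone gave 1775, 3418, 1456 and 197. Quiescent eggs differed from 7 h eggs in 69 of 1682 genes and from 14 h eggs in 1065. The 42 h D library stood apart from its group: its rank correlation was 0.302 with the mean of the other 42 h libraries. It was 0.836 with the mean of 3 h eggs and 0.834 with that of quiescent eggs. Leaving it out of the fit raised most counts, and its effect is given with each comparison. The median-ratio and quantile rescalings given below were computed from the selected genes alone and take most genes as unchanged. They show how counts move but cannot decide the true balance of rises and falls. Changes are on the log2(value + 1) scale with standard errors, and levels are mean ± SD of the deposited values.

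**Figure D1:**
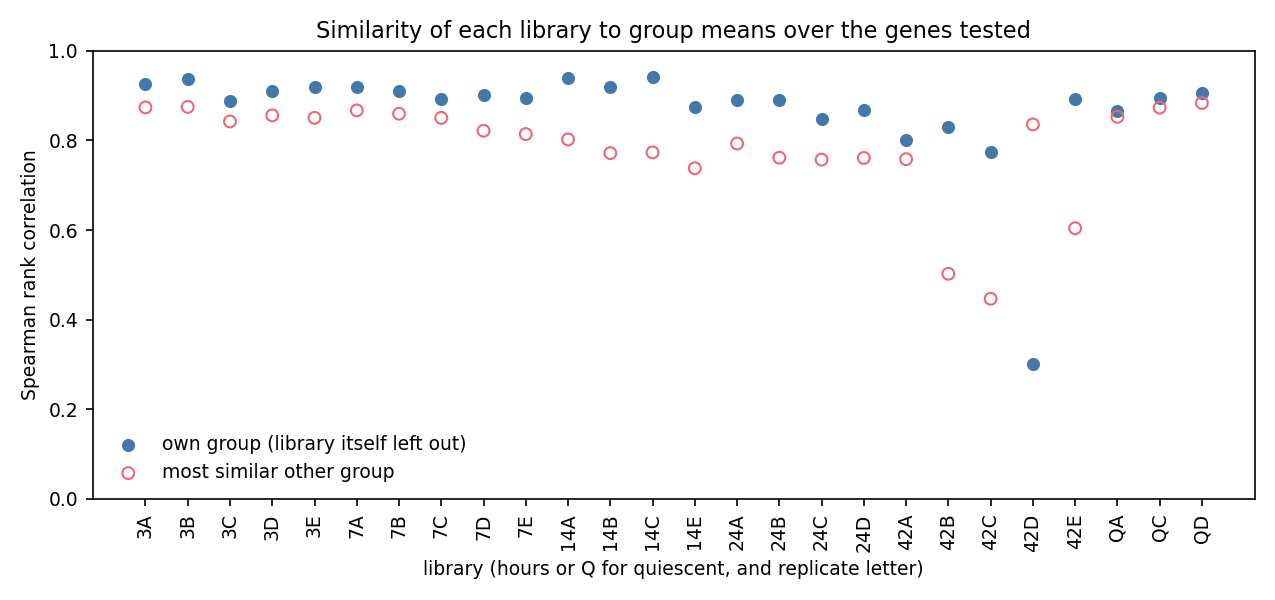
Spearman rank correlation (y axis) of each of the 26 libraries (x axis: hours, or Q for quiescent, and replicate letter) with group means over the genes tested. Filled points are the correlation with its own group, the library itself left out, and open points that with the most similar other group.

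**Figure D2:**
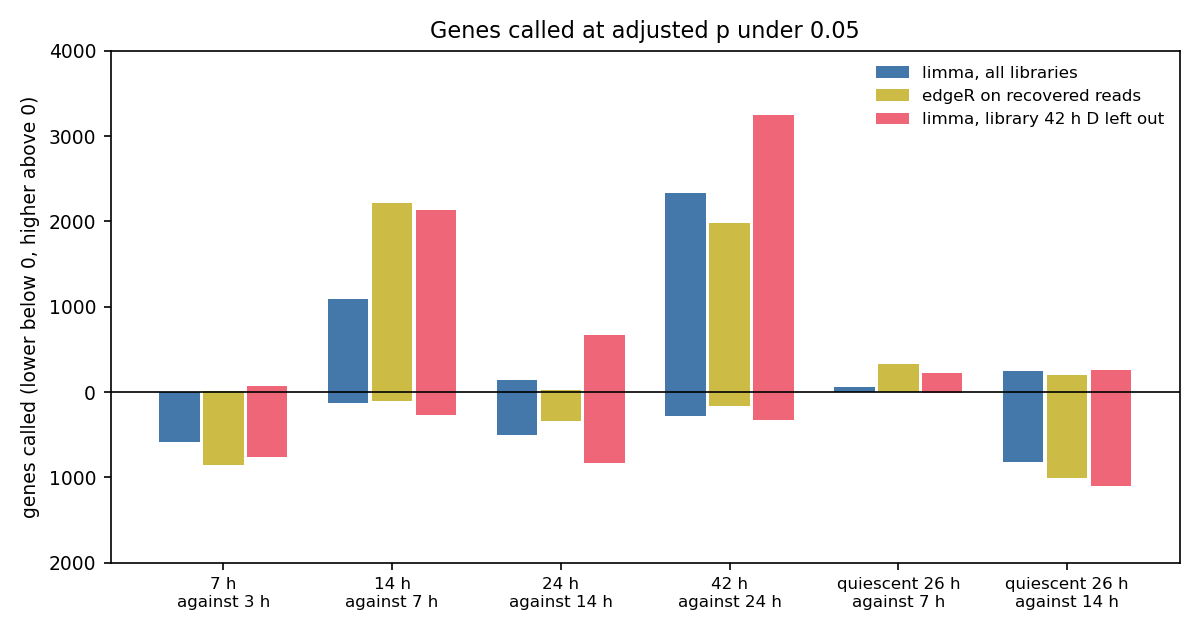
Genes called higher (above 0) and lower (below 0) in each of the 6 comparisons at an adjusted p under 0.05, drawn as bars for limma on all libraries, edgeR on recovered reads and limma without the 42 h D library. The y axis is the number of genes.

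From 3 h to 7 h, some transcripts of histones and cyclins fell, as counted below. A linker histone match (DN3534_c3_g1), of the proteins that bind DNA between nucleosomes, fell from 375 ± 37.3 to 11.4 ± 3.36 (n = 5 each, log2 change -4.96 ± 0.55), and a second one (DN4693_c1_g1) from 61.6 ± 5.64 to 1.88 ± 0.514. Cyclin B (DN1814_c0_g1) and cyclin A2 (DN5561_c0_g1) matches, which drive entry into and passage through mitosis, fell by 2.15 and 1.13. A Kazal-type protease inhibitor (DN4817_c0_g1) fell from 27.7 ± 3.21 to 0.735 ± 0.170, and 3 genes with a C-type lectin domain fell as well, among 7 of 26 tested with that domain (Fisher's exact adjusted p = 0.226). The falls were 3.29 for DN2045_c0_g1, 3.17 for DN3172_c1_g1 (156 ± 12.8 to 16.5 ± 2.26) and 3.05 for DN2195_c1_g1. A copper-zinc superoxide dismutase match (DN829_c1_g1), which removes superoxide, fell from 41.0 ± 4.62 to 5.37 ± 0.943. Of 25 histone genes 8 fell (12 adjusted over the list alone; camera adjusted p = 1.8e-05, and adjusted p = 0.0122 with an estimated correlation). This was adjusted p = 0.124 with an estimated correlation once 42 h D was left out. DN11161_c0_g1, also a linker histone match, was among the genes that fell (-2.22). Of 7 cell cycle genes 4 fell (5 adjusted over the list alone; adjusted p = 0.00997, adjusted p = 0.371 with an estimated correlation). The cell cycle falls came to 2 after median-ratio rescaling and 1 after quantile normalization. Of 5 patterning factors 3 fell (3 adjusted over the list alone; adjusted p = 0.0191, adjusted p = 0.0702 with an estimated correlation). Among them were matches to the signal protein Wnt8 (DN13388_c0_g1, -1.12) and the homeodomain protein HXA3A (DN7672_c0_g1, -1.29). The patterning falls came to 3 after median-ratio rescaling and 1 after quantile normalization. The name pattern of this list had caught 33 genes, of which 14 were kept. With the members left out by name put back in all lists, 3 lists passed the camera threshold at 7 h in place of 4. Among proteases of digestion and hatching 4 of 52 fell (4 adjusted over the list alone), including a trypsin match (DN7325_c0_g1, 6.52 to 0.290) and a match to phenoloxidase-activating factor 2 (DN557_c0_g1, 7.24 to 2.19). Of 13 lipid and yolk genes 2 fell (2 adjusted over the list alone): a pancreatic lipase match (DN4455_c0_g1, 8.65 ± 0.481 to 0.350 ± 0.0718) and an apolipoprotein-domain gene (DN19657_c0_g1, -0.84). Chaperones fell in 3 of 44 (2 adjusted over the list alone), with small heat shock proteins DN21453_c0_g1 (-0.85) and DN55100_c0_g1 (-0.78). Antioxidants fell in 1 of 18 and cuticle genes in 3 of 58, with DN794_c0_g1 (-2.02) and DN4493_c0_g1 (-1.87). Of 149 muscle genes 3 fell (0 adjusted over the list alone), with myosin heavy chain matches DN5090_c0_g1 (4.57 to 0.0768) and DN18174_c0_g1 (-1.36). The list as a whole moved up in camera (median 0.31, adjusted p = 1.8e-05, adjusted p = 0.987 with an estimated correlation). Of it 23 rose and 5 fell after median-ratio rescaling, 52 and 2 after quantile normalization, and 13 and 9 without 42 h D. Proteases came to 0 rises and 17 falls after median-ratio rescaling, 0 and 18 with edgeR, and 3 and 2 after quantile normalization. Lipid genes came to 1 and 4 after median-ratio rescaling, 0 and 3 with edgeR, and 3 and 2 after quantile normalization. Cuticle genes came to 1 and 9, 0 and 9, and 4 and 4 in that order. No member was called in the nervous system (21), respiration (6) and dormant-cyst stress (4) lists, nor among 324 ribosome genes, of which edgeR called 99 lower, median-ratio rescaling 47 and quantile normalization 15. Of all genes tested 11.1% fell. In total 5 genes rose and 579 fell, with 848 at an unadjusted p under 0.05; edgeR called 14 and 854. The 5 that rose carry no name and are listed because they are so few, a choice made after their values were seen. They are DN28493_c0_g1 (5.05 to 12.6), DN246_c0_g1 (4.57 to 9.71), DN11019_c0_g1 (1.86 to 5.30), DN37510_c0_g1 (1.10 to 2.39) and DN20563_c0_g1 (0.732 to 2.30). The excess of falls moved when these selected genes were rescaled. After median-ratio rescaling 191 rose and 859 fell, and 585 and 484 after quantile normalization, which moved the median change by 0.21. Without 42 h D 69 rose and 757 fell, with the spread of the 3 h and 7 h libraries alone 337 and 1438, and leaving out 3 h D left 1 that rose (3 without 3 h A, 3 h E or 7 h D).

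From 7 h to 14 h, when organs form, some genes of muscle, digestion and the ribosome rose, fewer than all of each list as counted below. Among named genes, myosin heavy chain matches rose steeply: DN5090_c0_g1 from 0.0768 ± 0.172 (n = 5) to 62.8 ± 37.1 (n = 4; log2 change 5.71 ± 0.73), and DN7006_c0_g1 to 33.4 ± 19.6 from a group listed at 0. A trypsin match (DN10880_c0_g1) rose from 5.08 ± 6.69 to 183 ± 93.6, the match to phenoloxidase-activating factor 2 (DN557_c0_g1) from 2.19 ± 1.68 to 61.7 ± 29.6, and a match to the crustacean cysteine protease crustapain (DN2972_c0_g1) from 0.507 ± 0.555 to 24.1 ± 12.3. Transcripts of H3.3 histone matches fell, DN2548_c1_g1 from 136 ± 17.3 to 48.2 ± 6.02 and DN4222_c1_g1 from 243 ± 61.3 to 87.8 ± 12.3. Of 149 muscle genes 44 rose (45 adjusted over the list alone; camera adjusted p = 4.0e-04, adjusted p = 0.832 with an estimated correlation). Examples are a myosin regulatory light chain (DN2072_c1_g2, 3.05 ± 0.223 to 39.7 ± 13.8) and DN585_c0_g1 (0.0144 to 9.98). For this list median-ratio rescaling gave 39 rises and 28 falls with a median of -0.22. Of 52 proteases 24 rose (29 adjusted over the list alone; adjusted p = 0.00135, adjusted p = 0.832 with an estimated correlation). One was a match to coagulation factor X, a trypsin-like protease (DN1476_c0_g1, 1.89 to 34.0). Of 324 ribosome genes 153 rose (171 adjusted over the list alone; adjusted p = 3.8e-09, adjusted p = 0.832 with an estimated correlation), such as DN25180_c0_g1 (1.56) and DN129634_c0_g1 (0.97). A plant, fungal, protist or bacterial best match was held by 147 of all genes that rose. Of the 324 ribosome genes 203 had such a match and 118 an animal one. Their levels were low: the 203 summed to 18.4 at 7 h and 260 at 14 h, and the 118 to 11.95 and 145. Which organism the ribosome and muscle transcripts came from was not determined. Chaperones rose in 14 of 44 (16 adjusted over the list alone), with the small heat shock matches DN3843_c0_g1 (0.592 to 13.2) and DN12651_c0_g1 (0.187 to 2.30). Cuticle genes rose in 12 of 58 (12 adjusted over the list alone; 38 without 42 h D), near the 21.1% of all genes tested that rose, with chitinase matches DN14546_c0_g1 (2.08) and DN5228_c0_g1 (2.33). Among 25 histones 6 rose and 2 fell (7 and 3 adjusted over the list alone). An H3 match (DN41657_c0_g1) reached 6.19 ± 0.769 from 0.0682 ± 0.0403, with an H4 match (DN9319_c1_g2) at 1.07. Ferritins, which store iron, rose in the dormant-cyst stress list, 3 of 4 members, with DN8240_c0_g1 (2.72 to 20.3) and DN4715_c0_g1 (1.90 to 9.71). Lipases DN19962_c0_g1 (2.21) and DN19962_c0_g2 (1.55) were among 3 of 13 lipid genes that rose. Single members rose among antioxidants (DN15497_c0_g1, 1.16; 0 adjusted over the list alone) and respiration (DN162457_c0_g1, 0.91; 4 adjusted over the list alone). So did 1 in the nervous system (the acetylcholine receptor match DN21732_c0_g1, 1.21; 0 adjusted over the list alone) and 1 in patterning (the Notch match DN7945_c0_g1, 0.64), in which HXA3A (DN7672_c0_g1) fell further, by 0.85. No cell cycle gene of 7 was called (4 lower after median-ratio rescaling, 3 after quantile normalization), although the list moved down (adjusted p = 0.0467, adjusted p = 0.702 with an estimated correlation). Several of these list counts depend on 42 h D: leaving it out gave 259 ribosome, 68 muscle, 33 protease, 24 chaperone, 9 nervous system, 8 antioxidant and 5 respiration genes higher. With edgeR these were 304, 57, 40, 27, 10, 8 and 6, and 27 cuticle and 12 histone genes were higher. The largest falls with a name were a reverse transcriptase of transposon type (DN5594_c0_g1, 132 ± 15.7 to 18.999 ± 6.01), a match to the yeast transcription factor subunit UAF30 (DN2252_c0_g1, -2.17), a glucose transporter (DN18580_c0_g1, -1.15) and a solute carrier (DN641_c0_g1, -1.01). Altogether 1095 rose and 129 fell, edgeR called 2220 and 108, and the spread of the 7 h and 14 h libraries alone gave 3106 and 312. Median-ratio rescaling moved the median change by -0.45 and gave 1098 and 643. Quantile normalization moved it by -0.58 and gave 800 and 1012, so that falls outnumber rises. Under the latter the balance also turned for histones (5 and 7), antioxidants (0 and 4), nervous system (0 and 5) and lipid genes (3 and 5). Without 42 h D, 2133 rose and 271 fell, and the falls came to 69, 70, 81 and 84 without 14 h E, 14 h B, 7 h E and 7 h C.

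**Figure D3:**
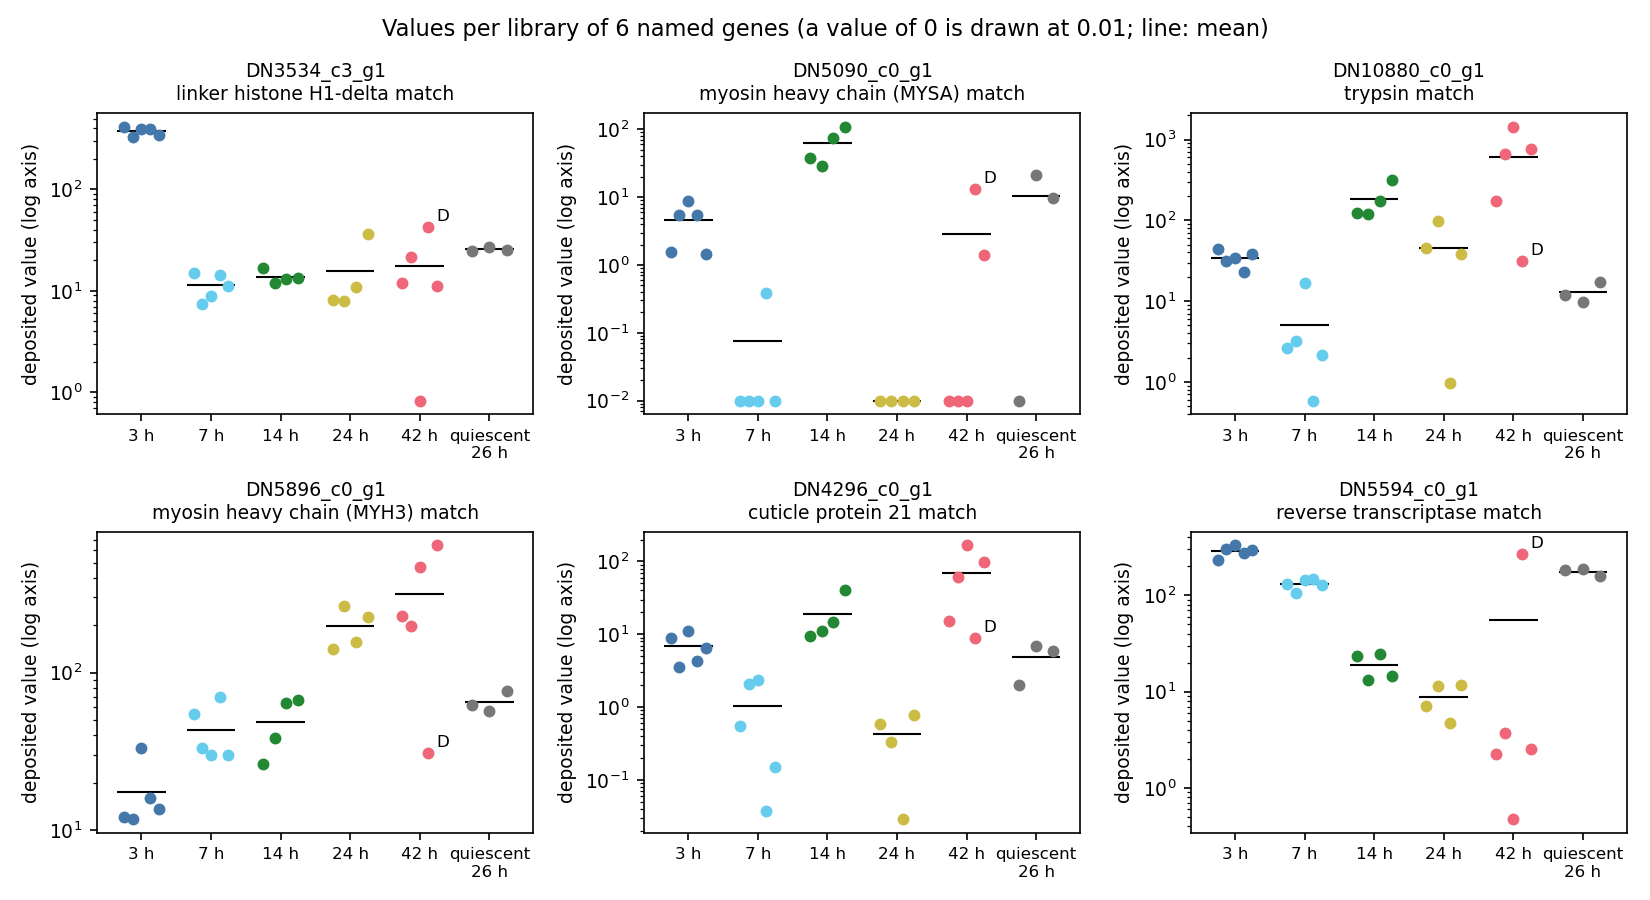
Deposited values (y axis, log scale) of 6 named genes in the 6 groups (x axis), with a listed 0 drawn at 0.01. Points are libraries, horizontal lines are group means, and D marks the 42 h D library.

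From 14 h to 24 h, as appendages form, some myosin genes rose while others fell. A MYH3 myosin match (DN5896_c0_g1) rose from 48.7 ± 19.7 to 197 ± 58.4 (n = 4 each, log2 change 2.04 ± 0.62), and DN2708_c0_g2 from 8.78 ± 3.45 to 31.7 ± 6.82, as did a muscle LIM protein (DN8502_c0_g1, 9.64 ± 1.82 to 31.5 ± 5.94) and DN37094_c0_g1 (11.9 to 38.8). Others fell: DN5090_c0_g1 from 62.8 ± 37.1 to a group listed at 0, DN7006_c0_g1 by 4.85, and DN159746_c0_g1 from 22.6 ± 11.4 to 0.418 ± 0.386. Of 149 muscle genes 13 rose and 38 fell (33 and 38 adjusted over the list alone), with DN585_c0_g1 (-3.33) and DN13563_c0_g1 (3.59 to 0.0747) among the falls. The median change of the list was 0.68, its mean -0.05 and its camera adjusted p 0.848. Leaving out 42 h D gave 69 and 38, median-ratio rescaling 56 and 38, and quantile normalization 50 and 38. Of 324 ribosome genes 60 fell and 0 rose (62 adjusted over the list alone; adjusted p = 2.7e-05, adjusted p = 0.957 with an estimated correlation), with DN25657_c0_g1 (-1.25) and DN30960_c0_g1 (-1.36); after quantile normalization 29 rose and 65 fell, and without 42 h D 13 and 95. Of 52 proteases 11 fell and 2 rose (18 and 2 adjusted over the list alone; adjusted p = 0.0129, adjusted p = 0.957 with an estimated correlation). DN557_c0_g1 fell from 61.7 to 7.04 and DN1476_c0_g1 from 34.0 to 5.20. The protease count was 3 higher and 22 lower without 42 h D, 2 and 24 after median-ratio rescaling, 8 and 17 after quantile normalization, 1 and 9 with edgeR, and 2 and 5 with the replicate block. An astacin-type metalloprotease (DN17897_c0_g1, 0.79) and a trypsin match (DN8063_c0_g1, 1.06) rose. Small heat shock matches DN3843_c0_g1 (-3.21) and DN12651_c0_g1 (-1.50) were among 5 of 44 chaperones that fell, and an HSP70 match (DN1373_c1_g1, 10.3 ± 2.18 to 25.6 ± 3.06) was the 1 that rose (5 higher and 7 lower without 42 h D). Cuticle genes fell in 6 of 58 with 0 rises (15 rises and 8 falls after quantile normalization, 10 and 8 without 42 h D), with chitinase matches DN14546_c0_g1 (-1.54) and DN5228_c0_g1 (-2.06), and histones in 2 of 25, DN41657_c0_g1 (-1.40) and DN9319_c1_g2 (-0.94). Of 13 lipid and yolk genes 2 rose, a vitellogenin match (DN10000_c0_g1, 1.87 to 4.80) and DN3043_c2_g1 (0.47), and 2 fell, lipases DN19962_c0_g2 (-1.25) and DN19962_c0_g1 (-1.56). No member was called in the cell cycle, antioxidant, respiration, patterning, nervous system and dormant-cyst stress lists. Genes with ankyrin repeats fell, DN16633_c0_g1 from 27.4 ± 5.16 to 1.07 ± 1.18 and DN30880_c0_g1 from 40.4 ± 10.5 to 2.09 ± 1.34. A match to a chloroplast protein of unknown function (DN16015_c0_g1, 2.56) and an actin match (DN8377_c0_g1, 1.78) rose. The chloroplast match read 0 to 2.44 at 14 h and 7.96 to 16.9 at 24 h, but also 0.366 to 48.8 within the 7 h libraries. In total 147 rose and 500 fell (9.61% of the genes tested), edgeR called 30 and 338, and the spread of the 14 h and 24 h libraries alone gave 615 and 841. After quantile normalization, which moved the median change by 0.12, 885 rose and 615 fell, so rises outnumber falls. Median-ratio rescaling gave 507 and 747, and leaving out 42 h D gave 672 and 835. Rises came to 57 to 94 without any 1 of 14 h A, B, C and E or 24 h A, B and C.

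**Figure D4:**
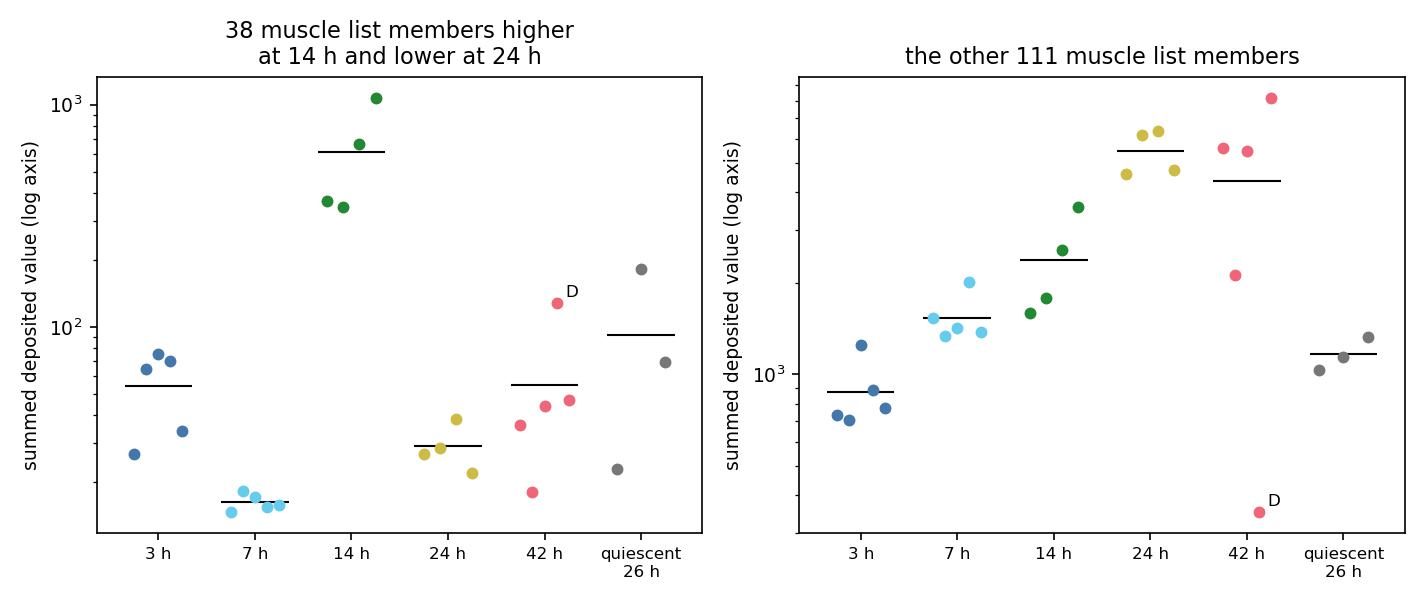
Sum of the deposited values of the 38 muscle genes that rose at 14 h and fell at 24 h, and of the other 111 muscle genes, in every library. Points are libraries by group (x axis), horizontal lines are means, D marks the 42 h D library, and the y axis is on a log scale.

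From 24 h to 42 h, before hatching, some chaperones, antioxidants, proteases and genes of the ribosome rose, and fewer of each after rescaling, as counted below. Among named genes, 3 cuticle protein matches rose steeply: DN4296_c0_g1 from 0.430 ± 0.323 (n = 4) to 70.2 ± 65.3 (n = 5; log2 change 4.97 ± 0.63), DN4493_c0_g1 from 0.639 to 55.6 and DN4852_c0_g1 from 0.124 to 24.2. Of the glutathione S-transferase matches, enzymes that conjugate toxic compounds, the named ones that rose were DN7332_c0_g1 (0.613 ± 1.17 to 67.8 ± 61.1) and DN5664_c0_g1 (3.11). Heat shock proteins that rose were DN1676_c1_g1 (HSP70 type, 8.33 ± 2.45 to 75.9 ± 37.1) and DN1337_c0_g1 (HSP27 match, 2.04 ± 0.0717 to 22.2 ± 11.4). Some myosins fell, DN7660_c0_g1 from 71.5 ± 24.96 to 9.04 ± 14.0 and DN12625_c0_g1 from 49.1 ± 21.97 to 6.24 ± 9.53. Of 25 genes with a myosin head domain 14 fell and 3 rose. The MYH3 match DN5896_c0_g1 read 140 to 264 at 24 h, 198 to 645 in 42 h A, B, C and E, and 30.6 in 42 h D. Levels at 42 h spread widely between libraries: DN4296_c0_g1 read 8.86 in D, 15.1 in A, 61.6 in B, 98.1 in E and 167 in C. DN7660_c0_g1 read 33.3 in A and between 0.713 and 8.65 in the others. Of 324 ribosome genes 208 rose and 1 fell (227 and 1 adjusted over the list alone; adjusted p = 3.5e-06, adjusted p = 0.900 with an estimated correlation). Examples are DN128591_c0_g1 (1.74) and DN68348_c0_g1 (0.80) up and DN6488_c12_g1 (-0.91) down. Of the 324, 203 had a plant, fungal, protist or bacterial match and 118 an animal one, and their organism of origin was not determined. Chaperones rose in 32 of 44 and fell in 1, the HSP70 match DN2067_c0_g1 (23.0 to 10.7; 33 and 1 adjusted over the list alone; adjusted p = 8.6e-04, adjusted p = 0.900 with an estimated correlation). Antioxidants rose in 13 of 18 (16 adjusted over the list alone) and proteases in 36 of 52 with 1 fall (37 and 1 adjusted over the list alone), both at adjusted p = 0.00344 and both at adjusted p = 0.900 with an estimated correlation. Among the proteases DN2606_c0_g1 (0.149 to 11.7) and DN2308_c0_g1 (2.35) rose and DN8063_c0_g1 fell (-1.60). Of 149 muscle genes 37 fell and 9 rose (30 and 7 adjusted over the list alone; adjusted p = 1.4e-18, adjusted p = 0.900 with an estimated correlation). A tropomyosin (DN9190_c0_g1, 1.34 to 11.7) and an actin match (DN60049_c0_g1, 0.93) rose, while DN288_c0_g2 (-2.27), DN2935_c0_g1 (-2.14) and the LIM protein DN8502_c0_g1 (-2.32) fell, as did the myosin match DN3836_c0_g2 (-2.49) outside the list. Without 42 h D the muscle count was 31 lower and 29 higher, and with edgeR 17 and 13. Leaving out 42 h D also gave 298 ribosome genes, 45 proteases, 38 chaperones and 17 antioxidants higher, where edgeR gave 184, 33, 27 and 13. Nervous system genes rose in 17 of 21 (17 adjusted over the list alone; adjusted p = 0.0626), among them a synaptotagmin (DN9017_c0_g1, 1.58) and an opsin (DN13864_c0_g1, 1.21). That count became 7 higher and 1 lower after median-ratio rescaling, and 3 and 3 after quantile normalization. Cuticle genes rose in 22 of 58 (20 adjusted over the list alone), a lower share than the 44.9% of all genes tested that rose. Without 42 h D 52 of the 58 rose, a higher share than the 3252 of 5201 genes that rose in that fit, so the order of the shares turns. Cuticle genes came to 18 higher and 5 lower after median-ratio rescaling, and 15 and 6 after quantile normalization. Histones rose in 9 of 25 (DN119730_c0_g1, 1.57, and DN147412_c0_g1, 1.17), also under the 44.9%, and in 2 and 1 after these rescalings and 4 with edgeR. Respiration genes rose in 5 of 6 (1 with edgeR; DN19752_c0_g1, 0.67, and DN88519_c0_g1, 1.01). Stress proteins of dormant cysts rose in 3 of 4 (ferritin DN4715_c0_g1, 6.33 to 22.6; aquaporin DN20903_c0_g1, 0.88) and patterning in 1 of 5 (DN7945_c0_g1, 0.60; -0.08 after quantile normalization). Of 13 lipid genes 6 rose (DN12215_c0_g1, 2.38; DN161297_c0_g1, 1.01) and 2 fell (vitellogenin DN10000_c0_g1, -1.23; DN3043_c2_g1, -0.71). Of 7 cell cycle genes the Cdc25 match DN2803_c0_g1 fell (-0.60; 0 adjusted over the list alone; list adjusted p = 0.0217, adjusted p = 0.900 with an estimated correlation), and 4 were lower and 1 higher without 42 h D. Sequestosome (DN2283_c0_g1, 1.13 to 23.3), an adaptor of autophagy, was the other large rise. In total 2337 rose and 277 fell, and edgeR called 1986 and 159. Median-ratio rescaling moved the median change by -0.62 and gave 1338 and 683, with 96 ribosome genes higher. Quantile normalization moved it by -0.71 and gave 946 and 858, with 47 of the 324, a lower share than that of all genes tested. Both left 0 respiration genes called, 20 chaperones higher and 3 lower, and 9 antioxidants higher. Proteases came to 29 higher and 3 lower and to 21 and 5, lipid genes to 6 and 2 and to 3 and 3, stress proteins to 2 and 0 higher, and muscle genes to 87 and 78 lower. With the spread taken from the 24 h and 42 h libraries alone 177 rose and 20 fell, and without 42 h D 3252 and 323.

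Quiescent eggs at 26 h, which per the labels had stopped at the stage of 7 h eggs, differed from these in 69 of 1682 genes with the spread shared over all groups, and in 712 (690 higher, 22 lower) with the spread of these 2 groups alone. Over the genes of the subitaneous table their rank correlation was 0.8473 to 0.8834 with the 3 h mean and 0.8525 to 0.873 with the 7 h mean. Small heat shock proteins, which hold unfolded proteins in solution, rose: DN3843_c0_g1 from 0.592 ± 0.441 (n = 5) to 6.04 ± 2.82 (n = 3; log2 change 2.11 ± 0.39), and DN1337_c0_g1 from 1.51 ± 0.774 to 7.76 ± 3.37. A match to ADAM29 (DN3637_c0_g1) stood at 33.2 ± 2.20 against 6.31 ± 0.591 in 7 h eggs, and read 31.6 to 37.5 in 3 h eggs. An ankyrin repeat gene (DN30880_c0_g1) rose from 2.16 ± 1.57 to 17.9 ± 15.2. Trypsin-like DN1476_c0_g1 (1.89 to 11.3) and DN557_c0_g1 (2.19 to 8.84) rose too, the 2 called of 31 proteases (2 adjusted over the list alone). Of 11 chaperones 3 rose (5 adjusted over the list alone; camera adjusted p = 0.0163, adjusted p = 0.937 with an estimated correlation), 0 after quantile normalization and 5 without 42 h D. No muscle gene of 44 was called (3 higher adjusted over the list alone), though edgeR called 15 higher and leaving out 42 h D gave 11 higher and 1 lower, while the list moved up (adjusted p = 0.0133, adjusted p = 0.937 with an estimated correlation). None of 257 ribosome genes was called, though edgeR called 106 higher. That list moved down against the others in camera (adjusted p = 0.0357, adjusted p = 0.937 with an estimated correlation) with a median change of 0.16, of the other sign. Without 42 h D 0 of 12 lists passed the camera threshold, in place of these 3. The other lists held 0 called genes: histones (1 higher adjusted over the list alone), antioxidants, respiration, patterning, cuticle, nervous system, lipid and stress proteins. In total 65 rose and 4 fell, 243 had an unadjusted p under 0.05, and edgeR called 332 and 4. The 4 that fell carry no name and are given because they are so few, chosen after their values were seen. They are DN74546_c0_g1 (6.93 to 1.46), DN5699_c0_g1 (4.199 to 0.879), DN2490_c0_g1 (3.10 to 0.335) and DN16500_c0_g1 (1.62 to 0.465). Quantile normalization, which moved the median change by -0.30, gave 5 higher and 23 lower. Leaving out 42 h D gave 219 and 8, and median-ratio rescaling gave 60 and 19, with 1 protease lower and 0 higher. Rises came to 26 without quiescent C and 31 without quiescent D, and the falls to 0 without either and to 2 without quiescent A or 7 h B, D or E.

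Against 14 h eggs, quiescent eggs had lower levels of muscle genes, though in fewer of them after rescaling. Trypsin DN10880_c0_g1 stood at 12.9 ± 3.72 (n = 3) against 183 ± 93.6 (n = 4; log2 change -3.63 ± 1.07), the myosin match DN5090_c0_g1 at 10.3 ± 10.6 against 62.8 ± 37.1, and crustapain DN2972_c0_g1 at 2.02 ± 1.49 against 24.1 ± 12.3. The transposon-type reverse transcriptase DN5594_c0_g1 stood higher, at 177 ± 15.7 against 18.999 ± 6.01, as did ADAM29 DN3637_c0_g1 (33.2 ± 2.20 against 4.56 ± 0.339). So did lectin DN3172_c1_g1 (29.8 against 6.65), the bZIP factor DN906_c0_g1 (10.6 against 2.09) and UAF30 match DN20787_c0_g1 (33.0 against 3.91). The last read 47.7 and 45.1 in quiescent C and D but 6.13 in quiescent A, near the highest 14 h value of 5.99. In 3 h eggs too these genes read above 14 h eggs, for example 233 to 332 for DN5594_c0_g1 and 138 to 172 for DN3172_c1_g1. Of 44 muscle genes 42 were lower (42 adjusted over the list alone; adjusted p = 3.2e-09, adjusted p = 0.685 with an estimated correlation). Examples are DN13563_c0_g1 (-1.61) and DN41878_c0_g1 (-1.51), and the myosin match DN7006_c0_g1 outside the list was lower too (-3.07). The list held 6 lower after median-ratio rescaling, 28 after quantile normalization and 20 with edgeR. Ribosome genes were lower in 133 of 257 (132 adjusted over the list alone; adjusted p = 0.0577), with DN18317_c0_g1 (4.04 to 0.371) and DN15684_c0_g1 (8.53 to 0.717), but in 1 after median-ratio rescaling (2 higher) and in 3 after quantile normalization (4 higher). Proteases were lower in 24 of 31 (26 adjusted over the list alone; adjusted p = 0.0972), with DN557_c0_g1 (-2.62) and DN13036_c0_g1 (-0.97), but in 1 after median-ratio rescaling, 5 after quantile normalization and 14 with the replicate block. A match to coagulation factor IX (DN44241_c0_g2, 15.7 to 0.730) fell outside that list. Cuticle genes were lower in 8 of 18 (3 adjusted over the list alone; DN14546_c0_g1, -1.60; DN5228_c0_g1, -2.01), near the 48.6% of all genes tested, and in 1 after either rescaling. Chaperones were lower in 5 of 11 (2 adjusted over the list alone; 1 higher and 0 lower after median-ratio rescaling), such as DN5898_c5_g1 (-1.02) and DN12651_c0_g1 (-0.86), the last of which reads 0.25 after median-ratio rescaling and 0.18 after quantile normalization. Of 10 histones 5 were lower (H3 DN41657_c0_g1, -2.22; DN9319_c1_g2, -0.93) and 1 higher (H2A match DN37137_c0_g1, 1.42), with 1 lower and 1 higher after either rescaling. Ferritins DN3233_c0_g1 (15.7 to 3.79) and DN8240_c0_g1 (20.3 to 3.88) were among 3 of 3 stress proteins lower (0 after median-ratio rescaling), and lipases DN19962_c0_g1 (-1.95) and DN9783_c0_g1 (-0.78) among 2 of 4 lipid genes (1 and 0 after the rescalings). Of 4 patterning factors HXA3A (DN7672_c0_g1, 1.27) and Wnt8 (DN13388_c0_g1, 0.36) were higher and the Notch match DN7945_c0_g1 lower (-0.60). Superoxide dismutase DN829_c1_g1 (10.03 against 2.31) was the 1 of 4 antioxidants called, the acetylcholine receptor DN21732_c0_g1 (-1.10) the 1 of 5 nervous system genes (0 adjusted over the list alone), and DN162457_c0_g1 (-0.70) the 1 of 4 respiration genes (0 adjusted over the list alone). In total 247 were higher and 818 lower, edgeR called 198 and 1003, the spread of these 2 groups alone gave 257 and 1267, and leaving out 42 h D gave 256 and 1095. The excess of falls turned under rescaling: median-ratio rescaling moved the median change by 0.83 and gave 275 and 75. Quantile normalization moved it by 0.63 and gave 237 and 153. Both were computed from genes selected as differing between these groups, so they cannot decide which direction prevails.

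Set against both stages, 39 genes were higher in quiescent eggs than in 7 h and 14 h eggs, 4 were lower than in both, and 11 lay above 7 h and below 14 h. The ADAM29 match DN3637_c0_g1, at 33.2 ± 2.20 against 6.31 ± 0.591 and 4.56 ± 0.339, was above both. Its quiescent libraries read 30.8 to 35.2, near the 31.6 to 37.5 of 3 h eggs, which these counts leave aside. The factor X match DN1476_c0_g1, at 11.3 ± 4.42, and the small heat shock match DN3843_c0_g1, at 6.04 ± 2.82, had 14 h levels of 34.0 ± 16.99 and 13.2 ± 6.31. Both comparisons share the quiescent libraries. Simulated unchanged quiescent libraries gave 0 genes above or below both, and independent lists of these sizes would share 9.55 above and 1.95 below. The genes had been selected as differing between quiescent eggs and these stages. Counts above the simulated ones were thus favored in advance and do not exclude chance. Quantile normalization left 3, 1 and 0, and median-ratio rescaling gave 32, 0 and 0. Without 42 h D the counts were 129, 8 and 67, and edgeR gave 27, 4 and 162. They fell to 20, 0 and 1 without quiescent C and to 24, 0 and 1 without quiescent D, and without quiescent A they were 35, 2 and 15.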

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

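The tests of explanations and of other splits of the libraries given here were all chosen only after the results were seen. Measures of libraries were compared within groups of 4 or 5 by the gap of the extreme library to its neighbor over the range, which chance exceeds in about 1 in 20 groups. Of 85 groups of library measures and list sums 8 stood out (4.25 expected by chance), and of 236 groups of named genes 20 (11.8 expected).

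The 42 h D library had a rank correlation of 0.302 with its own group, against 0.775 to 0.893 for the other 42 h libraries. A swap with another library of the series would need a partner, and 0 other libraries lay closer to another group than to their own. A mix of nauplii with undeveloped eggs would raise late genes. Their median level in 42 h D was 2.755% of that of the other 42 h libraries, inside the 2.08 to 3.13% of 3 h eggs. It lay above the 1.07 to 1.90% of quiescent eggs and the 0.337 to 0.9765% of 7 h eggs. The kind of eggs in such a mix is not known, so this test cannot decide on a small share of nauplii. A wrong label or undeveloped eggs stays open as a candidate explanation. The rank correlation of 42 h D with the 3 h mean was 0.836, against 0.127 to 0.439 for the other 42 h libraries, and with quiescent eggs 0.834. The linker histone match DN3534_c3_g1 read 42.5 in 42 h D, 328 to 416 in 3 h eggs and 24.4 to 26.9 in quiescent eggs. The reverse transcriptase match DN5594_c0_g1, nearer to 3 h eggs, read 269, 233 to 332 and 159 to 187 in that order. No biological explanation was tested. Of 100 splits of the 24 h and 42 h libraries, the real one included, 10 gave at least as many genes as the 2614 found, and the median of the others was 0. The highest, 3583, had 42 h D placed among the 24 h libraries and otherwise kept the stages apart. That split thus still holds the stage difference. By itself the count of splits does not exclude chance. Where 42 h D lay in the other splits was not examined.

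For the other comparisons the splits cannot exclude chance, because the genes in both tables had been selected as differing between these groups, which favors the real grouping. The real split alone (1 of 100) gave 584 genes for 7 h against 3 h (highest other 12), 1 of 100 gave 1224 for 14 h against 7 h (highest other 619), and 1 of 35 gave 647 for 24 h against 14 h (highest other 5). For quiescent eggs 1 of 56 splits gave 69 against 7 h (highest other 0), and 1 of 35 gave 1065 against 14 h (highest other 535).

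The total of the quiescent table was 29160 in 24 h D, against 7309 to 9047 in the other 24 h libraries. The histone list summed to 1071 in 42 h D (149 to 367 in the others), and the antioxidant and cuticle lists to 82.5 and 255.9 in 3 h C (55.9 to 62.1 and 146 to 169). At 7 h the muscle list summed to 2030 in D (1361 to 1546), and in C the nervous system list to 10.38 (13.9 to 15.3) and the proteases to 43.34 (15.7 to 21.4).

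Among named genes at 3 h and 7 h, DN4493_c0_g1 read 8.233 in 3 h C, DN7672_c0_g1 1.455 and DN25180_c0_g1 0.777 in 7 h A, DN585_c0_g1 0.061 in 7 h B, and DN5090_c0_g1 0.384 in 7 h D with the others listed at 0. In 7 h C, DN10880_c0_g1 read 16.92 (0.586 to 3.16 in the others), DN162457_c0_g1 0.021, DN5228_c0_g1 0.665 and DN30880_c0_g1 4.864. In 14 h E, DN7945_c0_g1 read 1.494, DN10000_c0_g1 2.388 and DN44241_c0_g2 32.29 (8.73 to 11.7 in the others). At 24 h, DN7006_c0_g1 read 0.202 and DN7332_c0_g1 2.369 in D, and DN13563_c0_g1 0.184, DN60049_c0_g1 0.803 and DN2803_c0_g1 2.439 in C. In 42 h A, DN7660_c0_g1 read 33.29, DN12625_c0_g1 23.26 (1.43 to 2.90 in the others) and DN8063_c0_g1 4.086.

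The subitaneous table also holds the quiescent libraries, and among its 3576 tested genes that the quiescent table lacks, 132 were called between quiescent and 14 h eggs (73 higher, 59 lower) and 2 between quiescent and 7 h eggs, where limma gave 142 at an unadjusted p under 0.05.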

How the results depend on the processing

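The alternatives without 42 h D, without 24 h D as well, without genes of plant, fungal, protist or bacterial match, and with lists restricted to animal matches or kept with the members left out by name, were tests chosen only after the results were seen, as were the replicate block, edgeR, DESeq2 and both rescalings for the genes set against both stages. Of the alternatives for counts and lists set out before the data were examined 129 lay over 1.5 times from the reported value and 187 within; of the added ones 34 and 52. No gene called in the reported fit was called in the opposite direction under any alternative run. Of 4010 alternative values for named genes called 3485 kept direction and call, 522 lost the call, and 3 turned: DN7945_c0_g1 from 24 h to 42 h reads -0.08 with quantile normalization, and DN12651_c0_g1 in quiescent against 14 h eggs 0.25 with median-ratio rescaling and 0.18 with quantile normalization. Replicate letters did not pair the libraries: deviations of same-letter libraries correlated at -0.466 to 0.501 over the comparisons, and the fit with the replicate block gave 79 lower for 14 h against 7 h, 2 lower for quiescent against 7 h, 2 below both stages and 7 between them. The first component of the deviations held 52.3% of their variance, and 32.2% without 42 h D.

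Counts that moved by over 1.5 times are given next as higher or lower genes, with consecutive stages named by the later time and quiescent eggs by the stage they were set against. A pseudocount of 0.1 gave 1818 higher at 14 h, 58 higher at 24 h and 125 higher against 7 h, and a pseudocount of 5 gave 9 higher at 7 h, 720 higher at 14 h and 2 lower against 7 h. No filter gave 1738 higher at 14 h, 882 lower at 24 h, 4977 higher at 42 h and 1417 lower against 14 h. A filter at a value of 5 gave 517 higher at 14 h, 64 higher and 194 lower at 24 h, 697 higher and 145 lower at 42 h, and 332 lower against 14 h. Median-ratio rescaling gave 191 higher at 7 h, 643 lower at 14 h, 507 higher at 24 h, 1338 higher and 683 lower at 42 h, 19 lower against 7 h and 75 lower against 14 h, with 0 below both stages and 0 between. Quantile normalization gave 585 higher at 7 h, 1012 lower at 14 h, 885 higher at 24 h, 946 higher and 858 lower at 42 h, 5 higher and 23 lower against 7 h, and 153 lower against 14 h, with 3 above both stages, 1 below both and 0 between. C, D and E libraries alone gave 0 higher and 242 lower at 7 h, 481 and 1 at 14 h, 12 and 238 at 24 h, 21 and 27 at 42 h, 0 and 0 against 7 h, and 37 and 312 against 14 h; A and B libraries alone gave 260 and 254 at 24 h, 112 lower at 42 h, 17 and 0 against 7 h and 386 lower against 14 h. Only the 2 groups compared gave 337 and 1438 at 7 h, 3106 and 312 at 14 h, 615 and 841 at 24 h, 177 and 20 at 42 h, 690 and 22 against 7 h, and 1267 lower against 14 h. Without trend and robust 17 were higher at 7 h. An adjusted p under 0.001 and a log2 change of 2 gave 0 and 197, 211 and 5, 2 and 79, 248 and 33, 4 and 0, and 22 and 66, with 2 above both stages, 0 below both and 0 between. Without 42 h D 69 were higher at 7 h, 2133 higher and 271 lower at 14 h, 672 and 835 at 24 h, and 219 and 8 against 7 h, with 129 above both stages, 8 below both, 67 between, and 451 genes highest at 24 h. On recovered reads edgeR gave 14 higher at 7 h, 2220 higher at 14 h, 30 higher at 24 h, 159 lower at 42 h, 332 higher against 7 h and 162 between. DESeq2 gave 55 and 1057 at 7 h, 2399 higher at 14 h, 440 and 11 against 7 h, 11 below both and 246 between. Without 42 h D edgeR gave 159 and 1266 at 7 h, 2896 and 250 at 14 h, 517 higher at 24 h, 542 and 13 against 7 h, 88 above both, 13 below both and 293 between.

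Leaving out each replicate in turn gave 1 to 6 higher and 521 to 557 lower at 7 h, 897 to 984 and 69 to 113 at 14 h, 57 to 110 and 385 to 478 at 24 h, 1938 to 3252 and 211 to 366 at 42 h, 26 to 78 and 0 to 3 against 7 h, and 207 to 238 and 556 to 754 against 14 h. For the genes set against both stages only the quiescent libraries were left out in turn, which gave 20 to 35 above both, 0 to 2 below both and 1 to 15 between. Lists past the threshold came to 4, 4, 2, 6, 3 and 1 over the 6 comparisons. They came to 1, 0, 0, 0, 0 and 0 with an estimated correlation, and without 42 h D to 0 against 7 h and 2 against 14 h. With fry, which asks whether a list moves 1 way on balance and does not compare it with other genes, they came to 3, 7, 0, 11, 1 and 7.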

Other observations

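The enrichment tests of protein domains and the tests of explanations in this part were chosen only after the results were seen. The domain tests count the genes of the assembly as independent. Members of a domain that move together, as fragments or copies of 1 gene would, make these p-values too small. For the gene lists, camera with an estimated correlation left 0 of 13 past the threshold at 42 h. Over 256 tests (Fisher's exact, Benjamini-Hochberg), genes with a myosin head domain fell from 24 h to 42 h in 14 of 25 (adjusted p = 7.2e-10), and those with a myosin tail in 11 of 31 (adjusted p = 3.4e-05). Myosin tail genes also fell at 24 h, in 12 of 31 (adjusted p = 5.1e-04). Trypsin domains rose at 14 h in 21 of 35 (adjusted p = 3.6e-05) and fell at 24 h in 10 of 35 (adjusted p = 0.0226). Genes with the Ank_2 domain of ankyrin repeats, which bind other proteins, fell at 7 h in 8 of 19 (adjusted p = 0.0109), rose at 14 h in 13 of 19 (adjusted p = 4.8e-04) and fell at 24 h in 10 of 19 (adjusted p = 1.3e-04). Those with the ankyrin domain Ank_4 did so in 3, 5 and 4 of 9 (adjusted p = 0.478, 0.246 and 0.0993). Fibronectin type 2 domains rose at 14 h in 7 of 8 (adjusted p = 0.00336) and fell at 24 h in 7 of 8 (adjusted p = 3.6e-05). At 42 h the cytochrome P450 genes, enzymes that oxidize small molecules, rose in 10 of 10 (adjusted p = 0.00773) and methyltransferase genes of 1 family in 11 of 11 (adjusted p = 0.00381). Quiescent eggs had lower levels than 14 h eggs in 13 of 13 genes with a myosin tail (adjusted p = 0.00259) and 20 of 24 with a trypsin domain (adjusted p = 0.00962). These tests use the 818 genes called lower without rescaling. Median-ratio rescaling gave 75 lower, among them 6 of 44 muscle genes and 1 of 31 proteases. The domain rises at 42 h likewise use 2337 genes called higher, against 1338 after median-ratio rescaling and 946 after quantile normalization. Those at 14 h use 1095, against 1098 and 800. No domain test was run after rescaling.

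A set of 38 muscle genes rose at 14 h and fell at 24 h, with a summed value of 614 ± 342 at 14 h (n = 4), 16.2 ± 1.41 at 7 h (n = 5), 54.2 ± 22.3 at 3 h (n = 5) and 29.0 ± 7.00 at 24 h (n = 4), while the other 111 muscle genes summed to 5458 ± 939 at 24 h. Up to 24 h 481 genes took this course, including these 38, 60 ribosome genes and 11 proteases, with sums of 270, 4133 and 614 at 7 h, 14 h and 24 h, but at 42 h the 481 summed to 3065 ± 1400 and the 38 to 54.6 ± 42.6 (3399 and 36.2 without D). Against the normalization of the authors as the cause, 38 of the 38 were called in both comparisons after median-ratio rescaling. Expression by the embryo at organogenesis and maternal RNA at 3 h stay open, untested, as does RNA of other animals in the egg samples, because its test cannot decide: 3 h eggs correlated with 14 h eggs across these genes at 0.825 or more, but across the other 111 muscle genes at 0.973 to 0.983. Across the 38 genes quiescent C gave 0.960, quiescent D 0.951 and 42 h D 0.923. Quiescent A gave 0.536 and 7 h eggs 0.353 to 0.475, and the -0.163 to 0.317 of 42 h libraries without D rests on values near the floor (20 and 21 of the 38 listed at 0 in C and B).

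Of 291 ribosomal protein genes tested, 180 had a plant, fungal, protist or bacterial match and 109 an animal one. RNA of other eukaryotes in the egg samples stays open: 51 of 73 families held both genes with a higher mean at 14 h and genes with a higher mean at 42 h, where permutations gave a mean of 44.5 (1-sided permutation p = 0.0081, found and tested on the same data). That test does not separate the 2 kinds of match, whose list sums took the same course, 62.1, 18.4, 260, 156 and 852 from 3 h to 42 h against 32.4, 11.95, 145, 95.2 and 469 for animal matches, with a ratio of 1.415 to 2.315 over the libraries. Fragments of 1 gene of the copepod would move together, while genes of 1 family correlated at a median of 0.695 over the libraries, below the 0.736 between families. This speaks only to families as a whole, because a family can hold fragments of 1 gene beside other genes. Low values also weaken a correlation: the non-animal matches of the list had medians of 0.009 to 0.06 in the 7 h libraries. Paralogs in the copepod genome stay open, untested, as does the stage of the embryo.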
